A study of Homo sapiens with 6 samples.

How the data were processed

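Gene expression was measured in 6 human cybrid samples on Affymetrix arrays, with 3 arrays for each of the 2 groups. Per the labels' protocols, total RNA was extracted in triplicate from each group, copied into cDNA and labelled with biotin. The deposited values are one intensity per probe set and array, on a linear scale, and the authors summarised them with RMA, per the submitters' processing notes. RMA corrects background, normalizes arrays and combines the probes of a probe set. Its version, its settings and the scanner settings are not given in the sources used here. The deposited intensity values ran from 6.09 to 35790. The array medians were close, but the upper quartiles differed between arrays, so the columns do not share one distribution as a full quantile normalization would give.

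The plan made before the data were examined assumed log2 values. The deposited values were linear, so log2 was taken here, with no pseudocount because every value was above 0, and no other normalization was applied. Arrays carry no read depth, and their number limits the precision. Detection calls were not used here, so a low value is not separated from background, and a large fold change against a dim group depends on where that background lies.

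The annotation table paired 41097 of the 54675 probe sets with 1 gene symbol and 1801 with several, and it did not list the other 11777. Probe sets with several symbols or none were left out. Symbols were checked through gene identifiers against a reference gene table of the GRCh38.p14 assembly, which changed 0 symbols and left 54 probe sets unmatched. Each of the 19775 genes was represented by the probe set with the highest mean log2 value over the 6 arrays, chosen without regard to group. Of the 869 members of the fixed gene lists, 804 were measured in this way, and the rest were not analysed here. The 62 control probe sets stayed out of the tests and served as measures of RNA quality and hybridization.

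Differences are log2 values of 159/SUM159 minus A1/SUM159. They were tested with limma 3.58.1 in R 4.3.3, with a linear model of the 2 groups and moderated variances (lmFit and eBayes), and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene is called higher or lower at an adjusted p under 0.05. Values after ± are SDs over 3 arrays unless named as standard errors. The 30 gene lists were tested with camera at a preset correlation between genes of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The former rests on the 4 residual degrees of freedom of the fit, so it had little power here. A count "adjusted over the list alone" repeats the adjustment within one list.

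The rule for named genes was also fixed before the data were examined. It takes the 10 genes with the largest called difference in each direction whose groups do not overlap, the 4 members of smallest p in each list, and SRC, CPT1A, PPARGC1A, TK1, TK2 and the measured MT-ND and MT-CO genes. Uncharacterised loci and pseudogenes were left out of the first part. Any other gene in the text is said to have been chosen after its values were seen.

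The labels give both groups the replicate numbers 1, 2 and 3 without saying that a number marks a shared day or batch, so the fit has no block. Nothing in the labels says that the triplicates came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

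The fit was tested on simulated arrays of the same 19775 genes, in which 200 genes differed between the groups. It recovered 63 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and it called 11 unchanged genes. A DNA replication list shifted by -0.50 was called lower, and 0 of the other lists were called. The simulated genes varied independently, so that test does not show how the list test behaves when genes vary together.

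Alternatives fixed in advance were the mean of all probe sets of a gene, a test of each probe set, quantile normalization, centring on array medians, 2 other variance models, array weights, a filter on dim genes, a replicate block, each array left out in turn, and the other list tests. A pair of alternatives was chosen after seeing the data: leaving out both A1/SUM159 replicate 2 and 159/SUM159 replicate 1, and using 159/SUM159 replicate 1 alone against the 3 A1/SUM159 arrays. A1/SUM159 replicate 2 stood apart from its group, with SDs of log2 differences of 0.53 and 0.52 against the other arrays and 0.19 between those. Array 159/SUM159 replicate 1 had the smallest actin 3′ excess of its group (4.28). In the fit with that array alone only A1/SUM159 gives the spread, so a call lost there partly reflects fewer arrays. A list was counted as having turned direction when either the direction of its test or the sign of its median changed. That wording was settled after the values had been seen, and it counts more turns than either criterion on its own. The array weight estimate stopped with 1 warning that it had not converged.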

Results

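The data describe transmitochondrial cybrids, cells that combine the nucleus of one line with the mitochondria of another. The nuclear parent was SUM159, a triple negative breast cancer line, after it had been depleted of mitochondrial DNA (ρ0). A1/SUM159 cybrids received mitochondria from A1N4, a benign mammary epithelial line, and 159/SUM159 cybrids received them back from SUM159. Donor cells had been enucleated with actinomycin-D, and fused cells were selected with bromodeoxyuridine in medium lacking uridine. There were 3 arrays per group and 19775 genes with a named probe set. The comparison of the 2 groups asks how nuclear and mitochondrial gene expression differs with the origin of the mitochondria in one nuclear background. The study is known for an interest in mitochondrial energy metabolism, fatty acid oxidation and SRC.

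Expression differed widely between the cybrids. The genes highest in 159/SUM159 relative to A1/SUM159 included MCTP2, at 11.60 ± 0.19 against 5.05 ± 0.17 on the log2 scale (SD, n = 3 each; 93.5-fold; limma adjusted p = 3.24e-06). Next came MIR205HG, the host transcript of an epithelial microRNA, with a difference of 6.07, the peptidylarginine deiminase PADI3 (6.03), FEZ1 (6.02) and the copper-binding plasma protein gene CP (5.88). The Notch ligand DLL1 rose by 5.24 on the probe set used, to 9.24 in 159/SUM159. Another DLL1 probe set, which averaged 6.58 over all 6 arrays, was not called (0.45, limma adjusted p = 0.0591). Also higher were the protease inhibitor CSTA (5.23), SERPINF1 (5.10), the basal keratin KRT15 (5.06) and the heparan sulfate sulfatase SULF2 (5.00). In the other direction, the calcium channel subunit gene CACNA2D1 stood at 10.87 ± 0.16 in A1/SUM159 and 3.47 ± 0.32 in 159/SUM159, a difference of -7.40 (limma adjusted p = 3.24e-06). That rests on 1 of its 2 probe sets, as the other was not called (0.085, limma adjusted p = 0.765). The other averaged 7.02 over all 6 arrays, so it lay well below 10.87 in A1/SUM159 too. The secreted Wnt antagonist DKK1 fell by 7.10, and SOST, which encodes another Wnt antagonist, fell by 5.79. SPANXB1 (-6.69), PCDHB5 (-6.49), PCLO (-6.07), PNMA2 (-6.03), PLCB4 (-6.00), GDA (-5.99) and ANXA3 (-5.52) complete the 10 largest decreases. SPANXB1 has near-identical copies, which its probe set may not separate.

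**Figure D1:**
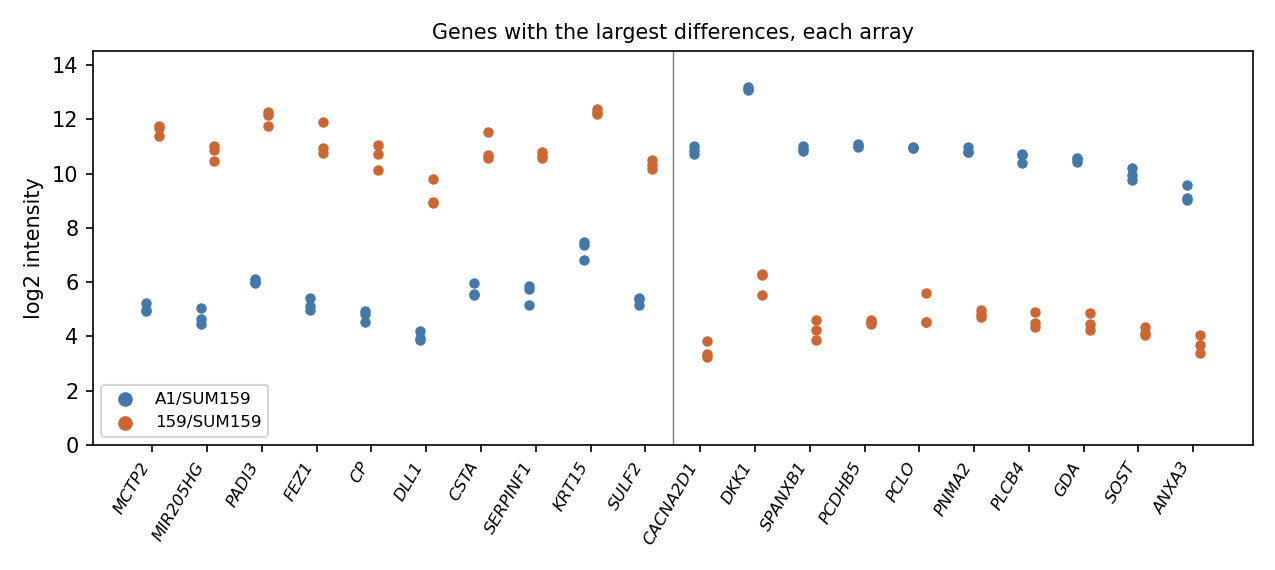
Log2 intensity of the 20 genes with the largest differences, one point per array, with A1/SUM159 in blue and 159/SUM159 in orange (n = 3 each). The groups do not overlap for any of them, from MCTP2, higher by 6.55, to CACNA2D1, with a difference of -7.40.

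In limma's test 3365 genes were higher and 4258 lower in 159/SUM159, together 38.5% of the genes tested. At a difference of at least 2-fold, 1221 were higher and 2816 lower, and at least 8-fold, 82 were higher and 202 lower. The groups did not overlap for 52.4% of all genes, where chance gives 10%. Probe sets of one gene often disagreed. Among called genes with at least 2 probe sets above the median level, all were called the same way for 410 of 1336 higher and 828 of 1896 lower genes. A probe set was called the opposite way for 143 and 176. Of those at least 8-fold apart, 32 of 33 higher and 49 of 71 lower genes had every probe set called the same way. Of the 133 named genes that were called, 64 had another probe set above the median level. For 26 such a probe set was not called the same way, and for 9 it lay within 1 log2 unit of the level of the one used. The mean of all probe sets gave less than the log2 value divided by 1.5 for 36 of the 133. The count of higher genes depended on single arrays, with 2125 without A1/SUM159 replicate 1, 1978 without A1/SUM159 replicate 3 and 2070 without 159/SUM159 replicate 2. Without both A1/SUM159 replicate 2 and 159/SUM159 replicate 1 it was 6242, and with 159/SUM159 replicate 1 alone it was 1464, beside 2684 lower genes. That last fit sets 1 array against 3, so only A1/SUM159 gives its spread.

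The control probe sets separated the groups as well. The actin signal at the 3′ end exceeded that at the 5′ end by 4.81 ± 0.48 log2 units in 159/SUM159 and by 1.55 ± 0.18 in A1/SUM159 (SD, n = 3 each), a measure that grows as RNA degrades or is copied incompletely. For GAPDH the excess was 2.03 ± 0.29 against 0.50 ± 0.10. The bioB hybridization spikes, added after the RNA was processed, read 10.03 ± 0.45 against 8.77 ± 0.34. For each of these 3 measures the groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 arrays can give. Array 159/SUM159 replicate 1 had the smallest actin excess of its group, at 4.28.

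**Figure D2:**
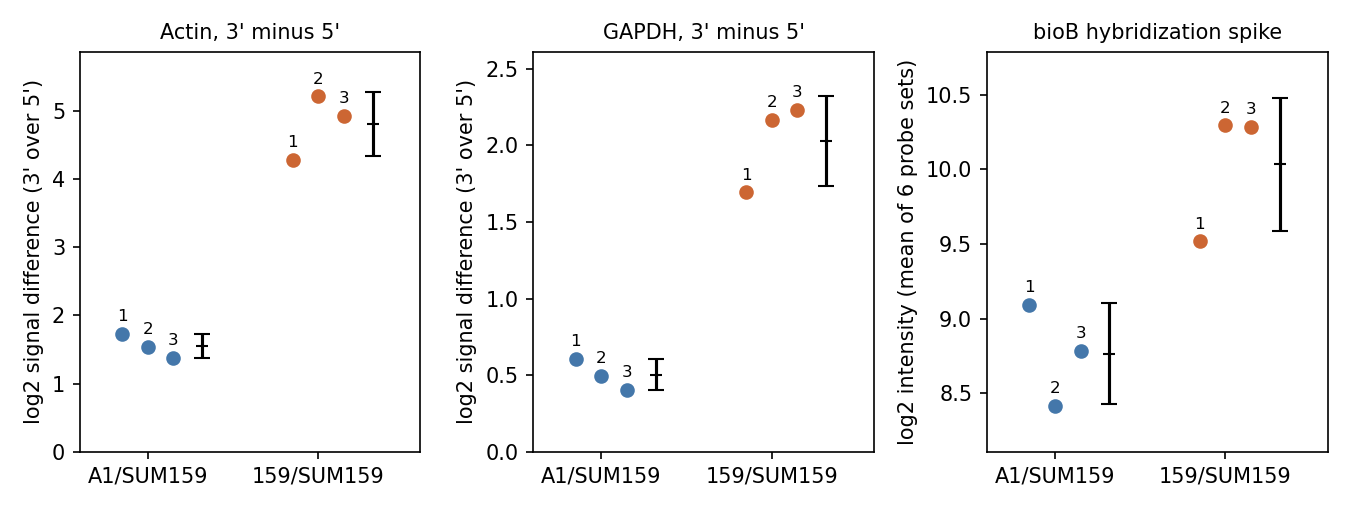
Control measures per array, with each replicate's number beside its point and the mean and SD at the right of each group (n = 3). The left and middle panels give the log2 excess of the 3′ over the 5′ signal of actin and GAPDH, and the right panel gives the mean log2 intensity of the bioB spikes. All 3 measures are higher on every 159/SUM159 array, with actin at 4.81 against 1.55.

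Transcripts of the mitochondrial genome itself read higher in 159/SUM159, most of them by too little to be called. Of 7 measured, MT-CO3, a subunit of cytochrome c oxidase, rose by 1.65 (limma adjusted p = 0.0118), from 10.33 ± 0.13 to 11.98 ± 0.84, and 6 were not called, with the same counts when adjusted over the list alone. Within 159/SUM159, MT-CO3 read 12.78, 12.05 and 11.11 on replicates 1, 2 and 3. The MT-CO3 probe set is of a kind that can also bind other transcripts. MT-ND4 (0.21), MT-CO1 (0.12), MT-CO2 (0.14), MT-ND2 (0.30) and MT-ATP6 (0.30) lay near the top of the intensity scale in both groups, where differences may be compressed. A dimmer MT-ATP6 probe set, not used in the test, was higher by 1.40 (limma adjusted p = 0.00237). MT-ND6, encoded on the other strand, differed by 0.55. The groups did not overlap for any of the 7, nor for 52.4% of all genes. The median difference of all genes was 0.12, so MT-CO1 and MT-CO2 were about as much higher as the typical gene. The list was not called (median 0.30, camera adjusted p = 0.145), but it was called higher with a variance trend (adjusted p = 0.0460), with each probe set tested (0.0460), with 159/SUM159 replicate 1 alone (0.0392) and with fry (0.0201). With an estimated correlation it was not (0.656). Quantile normalization turned MT-CO1 (-0.046) and MT-CO2 (-0.033) lower, neither of them called.

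Nuclear genes for the respiratory chain were mostly lower in 159/SUM159. Of 33 nuclear-encoded complex I genes 20 were lower, 1 higher and 12 not called (22 lower and 1 higher adjusted over the list alone). NDUFB11 (-2.18), NDUFA8 (-1.21) and NDUFA10 (-1.19) fell, although a dimmer NDUFA10 probe set was higher and the mean of its probe sets was not called (-0.15, limma adjusted p = 0.367). NDUFV2 was the exception at 1.69, and it lies in a run of neighbouring genes on chromosome 18 that were higher together. In complexes II to V, 22 of 37 genes were lower, 0 higher and 15 not called (27 lower adjusted over the list alone). Cytochrome c (CYCS) (-1.77), the ATP synthase subunit ATP5PF (-1.49), UQCR10 (-1.32) and COX7B (-1.16) fell. The mitochondrial ribosome had 55 of 73 genes lower, 1 higher and 17 not called (56 lower and 1 higher adjusted over the list alone), among them MRPS18C (-2.86), MRPS16 (-2.31), MRPS17 (-2.27) and MRPS7 (-1.84). Its 1 higher member was MRPS31, at 1.09, named after its value was seen. For the tricarboxylic acid cycle 15 of 26 genes were lower, 2 higher and 9 not called (17 lower and 2 higher adjusted over the list alone). IDH3A (-2.71) and the pyruvate dehydrogenase phosphatase PDP1 (-1.58) fell. Another IDH3A probe set, at a similar mean level over all arrays, was not called (-0.34), and the mean of the gene's probe sets was -1.42. The 2 higher members act at the entry to the cycle: pyruvate carboxylase (PC, 1.40) and the inhibitory kinase PDK3 (1.53), for which a dimmer probe set was lower.

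Camera called all of these nuclear lists lower. The medians were -0.75 for complex I (adjusted p = 7.72e-06), -0.81 for complexes II to V (adjusted p = 5.32e-06), -1.19 for the mitochondrial ribosome (adjusted p = 1.55e-15) and -0.69 for the tricarboxylic acid cycle (adjusted p = 0.00614). With an estimated correlation none of the 4 was called (adjusted p = 0.641, 0.656, 0.471 and 0.656, in the same order). Fry called complex I (adjusted p = 0.00846), complexes II to V (0.0284) and the mitochondrial ribosome (0.00212) lower. No other fit lost the camera calls of those lists. The tricarboxylic acid cycle call was also lost after quantile normalization (adjusted p = 0.0506), among genes above the median level (0.0694) and with fry (0.0537). These lists were lower on the arrays with the larger actin 3′ excess, 4.81 against 1.55. On 159/SUM159 replicate 1, with the smallest excess of its group, their medians were -0.55, -0.37, -0.94 and -0.38, in the same order as above.

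**Figure D3:**
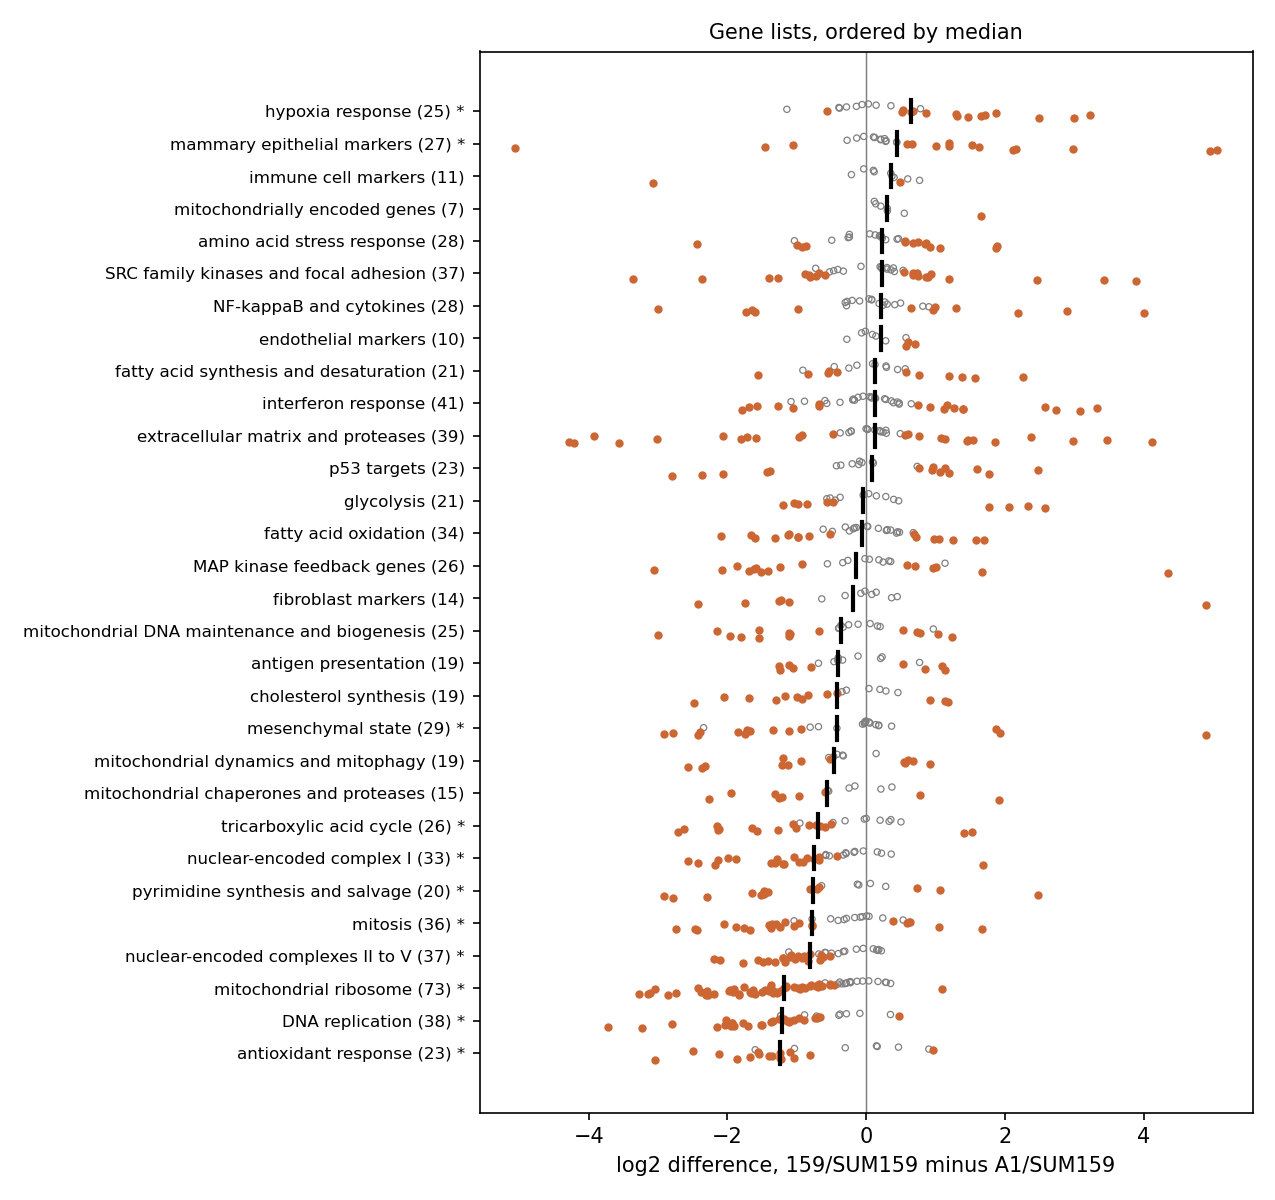
Log2 difference, 159/SUM159 minus A1/SUM159, of each measured member of the 30 gene lists, ordered by median (black bar), with the number of members in brackets. Filled points passed the adjusted p threshold over all genes, open points did not, and an asterisk marks the 11 lists camera called. The mitochondrial ribosome (median -1.19) and DNA replication (-1.21) lie near the bottom, and hypoxia response (0.64) at the top.

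Other mitochondrial lists leaned lower, with members both ways, and were not called as tested. For mitochondrial DNA maintenance and biogenesis, 10 of 25 genes were lower, 5 higher and 10 not called (10 lower and 6 higher adjusted over the list alone; median -0.37, camera adjusted p = 0.145). The deoxyguanosine kinase DGUOK (-1.55) and the single-strand binding protein SSBP1 (-1.96) fell, while the nuclear receptor ESRRA rose by 1.24. The other SSBP1 probe sets were not called (-0.48 and -0.39), and the mean of its probe sets was -0.94. TEFM differed by -1.80 on the probe set used and was higher on the other, and the mean of both was not called (-0.31, limma adjusted p = 0.143). PPARGC1A, a coactivator of mitochondrial biogenesis, differed by 0.97 and was not called (limma adjusted p = 0.0509). For dynamics and mitophagy, 8 of 19 genes were lower, 5 higher and 6 not called (10 lower and 5 higher adjusted over the list alone; median -0.47, camera adjusted p = 0.0773), with PHB1 (-2.57), the mitophagy kinase PINK1 (-2.37), FIS1 (-2.33) and MFF (-1.12) lower. Among mitochondrial chaperones and proteases, 7 of 15 were lower, 2 higher and 6 not called (8 lower and 2 higher adjusted over the list alone; median -0.56, camera adjusted p = 0.0773). HTRA2 (-2.26), DNAJA3 (-1.26) and CLPP (-1.21) fell, and AFG3L2, in the chromosome 18 run, rose by 1.91. Some fits did call these lists lower, but none of the 3 was called with an estimated correlation (adjusted p = 0.656 for each). Without 159/SUM159 replicate 1 dynamics and chaperones were called (adjusted p = 0.0131 for both). Without both that array and A1/SUM159 replicate 2 all 3 were, with adjusted p = 0.0241 for DNA maintenance, 0.0146 for dynamics and 0.0241 for chaperones. Fry called DNA maintenance (0.0462), and the mean of all probe sets gave a call for dynamics (0.0460). Array weights, whose estimate did not converge, called all 3 (0.0415, 0.0316 and 0.0311). With each probe set tested, the medians turned to 0.053 for DNA maintenance and 0.052 for chaperones.

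Fatty acid oxidation was divided. CPT1A, which controls entry of long-chain fatty acids into mitochondria, rose by 1.25 (2.38-fold, limma adjusted p = 0.00182; 0.41 for the mean of its 4 probe sets), and ACADVL, the first enzyme of long-chain oxidation, rose by 1.05. The peroxisomal thiolase ACAA1 rose by 1.58 and the lipid-sensing receptor PPARD by 1.70. These rises were read on the arrays with the larger actin 3′ excess, 4.81 against 1.55. Within 159/SUM159, ACAA1, PPARD and ACADVL were lowest on replicate 1, which has the smallest excess (ACAA1 10.46, against 10.83 and 11.04). CPT1A was highest there (10.63, against 10.24 and 10.06). Of 34 genes 7 were higher, 10 lower and 17 not called (8 higher and 10 lower adjusted over the list alone), and the list was not called (median -0.066, camera adjusted p = 0.853). In fatty acid synthesis 6 of 21 genes were higher, 5 lower and 10 not called, with the same counts when adjusted over the list alone (median 0.13, camera adjusted p = 0.575; fry 0.00846, estimated correlation 0.656). Its leading members were the lipogenic regulators MLXIPL (2.25) and SREBF1 (1.19), PNPLA3 (1.56) and ACSS2 (1.38). Cholesterol synthesis had 10 of 19 genes lower, 3 higher and 6 not called (10 lower and 4 higher adjusted over the list alone; median -0.42, camera adjusted p = 0.164), and was called lower with the mean of all probe sets (0.0144), with each probe set tested (0.00811), with array weights (0.0418) and without both A1/SUM159 replicate 2 and 159/SUM159 replicate 1 (0.0427), but not with an estimated correlation (0.656). IDI1 (-2.49) and INSIG1 (-1.30) fell, and TM7SF2 (1.17) and SREBF2 (1.13) rose, though a SREBF2 probe set at the same level was not called (0.45). Glycolysis had 4 of 21 genes higher, 6 lower and 11 not called (5 higher and 7 lower adjusted over the list alone; median -0.045, camera adjusted p = 0.970). The 4 higher genes were ENO2 (2.57), the glucose transporter SLC2A3 (2.32), PFKFB4 (2.06) and ALDOC (1.77). Another SLC2A3 probe set was not called (0.94, limma adjusted p = 0.0586).

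SRC, the tyrosine kinase of interest to the study, was higher in 159/SUM159, at 9.66 ± 0.23 against 8.46 ± 0.10 (SD, n = 3 each; 2.30-fold, limma adjusted p = 0.0013). This is the brightest of its 7 probe sets. The other 6, all dimmer, were not called (0.18 to 0.52), and the mean of all 7 was 0.45 (limma adjusted p = 0.0407). Within 159/SUM159, SRC read 9.44 on replicate 1 and 9.65 and 9.90 on replicates 2 and 3, which have the larger actin 3′ excess. An effect of RNA quality on SRC was therefore not separated from the group. Its relative YES1, in the chromosome 18 run, rose by 2.46, whereas FYN fell by 2.36. The integrins ITGB4 (3.89) and ITGA2 (3.42), receptors for laminin and collagen, were higher. Of 37 genes for SRC family kinases and focal adhesion, 12 were higher, 10 lower and 15 not called (13 higher and 11 lower adjusted over the list alone), and the list was not called (median 0.22, camera adjusted p = 0.671; fry 0.0433, estimated correlation 0.916).

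Mammary epithelial markers leaned higher in 159/SUM159. The basal keratins KRT15 (5.06) and KRT5 (4.95), the desmosomal plaque gene DSP (2.98) and SFN (2.12) rose. Of 27 markers 12 were higher, 3 lower and 12 not called (14 higher and 3 lower adjusted over the list alone; median 0.44, camera adjusted p = 0.00428), with adjusted p = 0.278 with an estimated correlation. The 3 lower members, named after their values were seen, were CD24 (-5.07), KRT7 (-1.46) and the tight junction gene OCLN (-1.06). The call was lost when each probe set was tested (median 0.21, adjusted p = 0.116).

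Mesenchymal genes were lower on balance. The contractile gene TAGLN (-2.91), COL1A1 (-2.42) and THY1 (-1.74) fell, although a dimmer COL1A1 probe set was higher and another TAGLN probe set was not called (0.48). COL3A1 went the other way, from 7.34 ± 0.07 to 12.24 ± 0.55, a difference of 4.90. Of 29 genes 11 were lower, 3 higher and 15 not called (13 lower and 3 higher adjusted over the list alone; median -0.42, camera adjusted p = 0.016), with adjusted p = 0.656 with an estimated correlation. The call was lost after quantile normalization (adjusted p = 0.0988), with the mean of all probe sets (0.056), among genes above the median level (0.145), with 159/SUM159 replicate 1 alone (0.143) and with each probe set tested, where the median turned to 0.018. The higher epithelial and lower mesenchymal lists were read on the arrays with the larger actin 3′ excess, 4.81 against 1.55. Fibroblast markers had 5 of 14 lower, 1 higher and 8 not called (6 lower and 1 higher adjusted over the list alone; median -0.19, camera adjusted p = 0.164; fry 0.0118, estimated correlation 0.656), and they share COL3A1, COL1A1, THY1 and PDGFRB (-1.12) with the mesenchymal list. For extracellular matrix and proteases 13 of 39 genes were higher, 12 lower and 14 not called, with the same counts when adjusted over the list alone (median 0.12, camera adjusted p = 0.811). The basement membrane collagen COL4A2 (4.12) and COL16A1 (1.86) rose, and COL8A1 (-4.22) and ADAMTS1 (-3.57) fell.

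Markers of other cell types were few. The leukocyte phosphatase PTPRC fell by 3.07 and ITGAM rose by 0.48, and the other 9 of 11 immune markers, such as CD74 (0.77) and TYROBP (0.60), were not called, also when adjusted over the list alone (median 0.35, camera adjusted p = 0.690). Of 10 endothelial markers CLDN5 (0.57), KDR (0.70) and CDH5 (0.60) were higher from low levels, 0 were lower and 7, such as EMCN (0.28), were not called, with the same counts when adjusted over the list alone (median 0.21, camera adjusted p = 0.362). Without A1/SUM159 replicate 1 the calls of ITGAM (limma adjusted p = 0.091), CLDN5 (0.0707), KDR (0.0731) and CDH5 (0.114) were lost, and they were lost without A1/SUM159 replicate 3 as well. Leaving out 159/SUM159 replicate 2 ended the calls of ITGAM (0.0631), KDR (0.0623) and CDH5 (0.133), replicate 3 those of ITGAM (0.0689) and CLDN5 (0.0551), and replicate 1 that of CDH5 (0.0724). The replicate block ended those of ITGAM (0.0863), CLDN5 (0.0671) and CDH5 (0.05002), median centring those of ITGAM (0.0573) and CDH5 (0.0912), and quantile normalization that of CDH5 (0.0827). That of ITGAM was also lost with the mean of its probe sets (0.0874) and with a variance trend (0.0519).

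DNA replication genes were lower in 159/SUM159. MCM10 (-3.73), the licensing factor CDC6 (-3.23), the helicase subunit MCM6 (-2.15) and UHRF1 (-1.70) fell. Of 38 genes 29 were lower, 1 higher (ORC6, 0.47, named after its value was seen) and 8 not called (33 lower and 1 higher adjusted over the list alone; median -1.21, camera adjusted p = 1.99e-12), with adjusted p = 0.278 with an estimated correlation. Pyrimidine synthesis and salvage, which supplies the nucleotides that ρ0 cells obtain from added uridine, had 12 of 20 genes lower, 3 higher and 5 not called, with the same counts when adjusted over the list alone (median -0.76, camera adjusted p = 0.00426; adjusted p = 0.278 with an estimated correlation). The ribonucleotide reductase subunit RRM2 (-2.91), uridine phosphorylase UPP1 (-2.78), CTPS1 (-2.29) and CAD (-1.52), which starts pyrimidine synthesis, fell. The thymidine kinase genes, whose products take up bromodeoxyuridine into the nucleotide pool, moved apart on the probe sets used. TK1 differed by -0.68 (limma adjusted p = 0.0186), and by -2.03 on its other probe set (limma adjusted p = 0.00034). The mitochondrial TK2 differed by 0.73 (limma adjusted p = 0.00671). Its other probe sets were not called (0.17 to 0.46), and the mean of all 4 was 0.44 (limma adjusted p = 0.036). On the probe set used, TK1 lost its call without A1/SUM159 replicate 1 (limma adjusted p = 0.0758) or replicate 3 (0.0739), after quantile normalization (0.154) and with the replicate block (0.0527), while the mean of its probe sets was -1.36 (0.000318).

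Mitotic genes were lower on balance, with 17 of 36 lower, 6 higher and 13 not called (18 lower and 6 higher adjusted over the list alone; median -0.78, camera adjusted p = 0.00426), with adjusted p = 0.656 with an estimated correlation. KIF4A (-2.46), SPC25 (-2.44) and the kinase PLK1 (-1.67) fell, and NDC80, in the chromosome 18 run, rose by 1.67. The call was lost after quantile normalization (adjusted p = 0.0541) and among genes above the median level (0.0758). The replication, pyrimidine and mitosis lists, like the mitochondrial ones, were lower on the arrays with the larger actin 3′ excess, 4.81 against 1.55. Within 159/SUM159 they did not all behave alike. On replicate 1, with the smallest excess, the replication median was -1.20, against -1.21 for the whole group. The pyrimidine median there was -0.85, against -0.76, and the mitosis median was -0.44, against -0.78.

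Antioxidant genes were mostly lower and hypoxia-response genes leaned higher. Thioredoxin reductase TXNRD1 (-3.04), TALDO1 (-1.87), the sulfiredoxin gene SRXN1 (-1.24) and the superoxide dismutase SOD1 (-1.22) fell. Of 23 antioxidant genes 15 were lower, 1 higher (GSR, 0.96, named after its value was seen) and 7 not called (17 lower and 2 higher adjusted over the list alone; median -1.24, camera adjusted p = 0.000122), with adjusted p = 0.656 with an estimated correlation. In the hypoxia list NDRG1 rose by 2.99, ANGPTL4 by 2.49, the angiogenic factor VEGFA by 1.66 and the carbonic anhydrase CA12 by 1.46. Of its 25 genes 14 were higher, 1 lower (SLC2A1, -0.56, named after its value was seen) and 10 not called, with the same counts when adjusted over the list alone (median 0.64, camera adjusted p = 0.00428), with adjusted p = 0.656 with an estimated correlation. The hypoxia call was lost without 159/SUM159 replicate 1 (median 0.49, adjusted p = 0.0988) and without both that array and A1/SUM159 replicate 2 (0.47, adjusted p = 0.223). Both lists moved on the arrays with the larger actin 3′ excess, 4.81 against 1.55. On 159/SUM159 replicate 1, with the smallest excess of its group, the hypoxia median was 1.01, against 0.64 for the whole group. The antioxidant median there was -0.82, against -1.24. Within 159/SUM159, only the antioxidant list therefore shifted further with the larger actin excess.

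The remaining lists were not called as tested, and each held large changes in both directions. For the amino acid stress response 10 of 28 genes were higher, 4 lower and 14 not called, with the same counts when adjusted over the list alone (median 0.23, camera adjusted p = 0.256), and the list was called higher after quantile normalization (0.0325), with 159/SUM159 replicate 1 alone (0.0392) and with fry (0.0367), but not with an estimated correlation (0.656). NUPR1 (1.86), SESN2 (1.07) and TRIB3 (0.91) rose and the tryptophan tRNA ligase WARS1 (-0.93) fell. TRIB3 lost its call with the mean of its probe sets (limma adjusted p = 0.128). Interferon-response genes divided into 11 of 41 higher, 7 lower and 23 not called, with the same counts when adjusted over the list alone (median 0.12, camera adjusted p = 0.425; fry 0.0222, estimated correlation 0.656). IFITM1 (3.08), OASL (2.74) and ISG15 (1.40) rose and IFI35 (-1.80) fell. Antigen presentation had 4 of 19 higher, 5 lower and 10 not called, with the same counts when adjusted over the list alone (median -0.40, camera adjusted p = 0.466), with TAPBP (1.13) and HLA-DRA (0.84) higher and the immunoproteasome subunits PSMB8 (-1.24) and PSMB10 (-1.05) lower. HLA-DRA lost its call with the mean of its probe sets (limma adjusted p = 0.174).

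Among NF-kappaB targets and cytokines, the feedback inhibitor TNFAIP3 rose from 6.34 ± 0.07 to 10.34 ± 0.18 (SD, n = 3 each; limma adjusted p = 7.6e-06) and ICAM1 rose by 2.19 (0.51 and not called on another probe set), while IL6 (-1.73) and NFKB1 (-1.61) fell. This list had 7 of 28 genes higher, 5 lower and 16 not called, with the same counts when adjusted over the list alone (median 0.21, camera adjusted p = 0.549; fry 0.00595, estimated correlation 0.656). Of 23 p53 targets 9 were higher, 5 lower and 9 not called (10 higher and 5 lower adjusted over the list alone; median 0.089, camera adjusted p = 0.691). The death receptor TNFRSF10B rose by 1.76, a call lost with the mean of its probe sets (limma adjusted p = 0.0549), and TIGAR (-2.81), TP53I3 (-2.37) and GADD45B (-2.07) fell. MAP kinase feedback genes had 6 of 26 higher, 10 lower and 10 not called (7 higher and 11 lower adjusted over the list alone; median -0.14, camera adjusted p = 0.433). The ERK phosphatase DUSP6 rose by 4.35, CCND1 (-1.51) and HBEGF (-1.41) fell, and DUSP4 was higher at 1.67 on the probe set used and lower on another, with no call for the mean of its probe sets (0.24, limma adjusted p = 0.264).

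Camera called 11 of the 30 lists, 2 higher and 9 lower. With an estimated correlation it called 0, and the smallest adjusted p was 0.278. That version also lost lists whose estimated correlation lay below the preset 0.01, mammary epithelial markers (-0.026) and pyrimidine synthesis (0.0068). For the other called lists the estimates lay above the preset, from 0.12 (DNA replication) to 0.61 (complexes II to V). They were 0.59 for antioxidant genes and 0.55 for hypoxia. If genes vary together that much, the camera p-values at the preset correlation are too small. With only 4 residual degrees of freedom behind the estimates, the losses neither show nor exclude that correlation between genes explains the calls. Fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 18.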

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

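The tests of RNA quality in this part were chosen after the results they bear on had been seen, and the quantile normalization test was chosen before. The labels describe no RNA quality measure, but the control probe sets hold a signal that differs between the groups. The actin 3′ excess over 5′ was 3.26 log2 units larger in 159/SUM159 than in A1/SUM159, and the GAPDH excess was 1.53 larger. The bioB hybridization spikes read 1.27 higher.

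Genes at least 8-fold higher in 159/SUM159, such as MCTP2 and KRT5, form the first pattern. Within the groups, over all 6 arrays, the median of the 82 genes had a slope of -0.096 per log2 unit of actin excess (95% interval -0.72 to 0.53), where 1.12 would be needed to give their median difference of 3.66. That argues against an RNA quality effect in proportion to the actin excess as the whole cause. Their median of -0.044 on 159/SUM159 replicates 2 and 3, which have the larger actin excess, relative to replicate 1 (17.7th percentile of expression-matched random lists) does not exclude an effect already complete on replicate 1. A difference that follows the mitochondrial donor, or one between the separately selected nuclear populations, stays open and was not tested.

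Lower nuclear-encoded mitochondrial, replication and pyrimidine lists form the second pattern. Within 159/SUM159, the mitochondrial lists read -0.40 on replicates 2 and 3 relative to replicate 1. Expression-matched random lists had a median of -0.22 and a 2.5th percentile of -0.33, and the value lay at their 0.08th percentile. Lower RNA quality may therefore account for part of the lists' difference. Random lists do not carry the correlation between list members, so their spread may be too narrow. The replication and pyrimidine lists gave -0.12, at the 30.0th percentile of random lists, and the slopes on actin excess were -0.46 (mitochondrial, interval -0.99 to 0.063) and -0.26 (interval -0.62 to 0.11). Both intervals hold 0 and the slope needed (-0.28 and -0.36), so by slope RNA quality and group cannot be told apart for either. Quantile normalization moved the mitochondrial median from -0.92 to -0.63, between the bounds set for that test, which leaves the authors' array scaling open as well. A biological effect of the mitochondrial donor is confounded with RNA quality in this design and stays open.

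With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The true split gave 3365 higher and 4258 lower genes, 1221 and 2816 at 2-fold or more. In each case 1 of the 10 splits reached the count, with 0 genes as the highest of the others. Every other split mixes the groups, so any large difference between them enters its spread. Few or no calls there follow from that, whatever the cause of the difference. For gene lists the true split called 11, another called 18, and 4 of the 10 splits called as many.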

How the results depend on the processing

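The 2 fits using selected arrays were chosen after seeing the data. Of 143 named genes 133 were called, and 128 were called in every fit that left out 1 array. Calls lost in other fits numbered 7 with the mean of all probe sets, 7 with 159/SUM159 replicate 1 alone (where only A1/SUM159 gives the spread), 4 with the replicate block, 2 after quantile normalization, 2 after median centring and 1 with a variance trend. Higher genes numbered 3365, with 1978 to 4287 over the fits without 1 array, 6242 without A1/SUM159 replicate 2 and 159/SUM159 replicate 1, and 1464 with 159/SUM159 replicate 1 alone, where 2684 were lower. Array weights gave 9400 higher and 6689 lower, but their estimate did not converge and put a weight of 32.7 on 1 array, so these counts are unstable. The mean of all probe sets gave 794 genes higher by at least 2-fold, against 1221. The replicate block gave 2339 higher and 3782 lower, but the numbers do not pair the arrays (correlations of deviations 0.26, -0.20 and -0.51). Lists called numbered 11, with 0 under an estimated correlation and 18 under fry. Median centring moved the median of all genes from 0.12 to 0.01. Higher genes made up 44.1% of calls, 49.4% after quantile normalization and 35.6% after centring. Detection above background was not analysed here, which limits dim genes. The cause was not tested unless stated.

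The test direction or the median of a list turned in 46 fits, 22 in the test alone, 11 in the median alone and 13 in both. All were in lists not called as reported, except mesenchymal state, and none of the turned values was called. The medians follow. With each probe set tested they were 0.053 (mitochondrial DNA maintenance), 0.15 (fatty acid oxidation), 0.040 (fatty acid synthesis), 0.052 (chaperones), -0.011 (SRC family), 0.018 (mesenchymal), 0.076 (fibroblast), 0.11 (immune), -0.018 (p53), -0.17 (matrix) and 0.034 (MAP kinase). Quantile normalization gave 0.10 (fatty acid oxidation), 0.046 (glycolysis) and 0.22 (immune), and it turned the single genes MT-CO1 (-0.046) and MT-CO2 (-0.033), neither called. Genes above the median level gave -0.14 (fatty acid oxidation), -0.045 (glycolysis) and -0.047 (interferon). With 159/SUM159 replicate 1 alone they were 0.036 (fatty acid oxidation), 0.14 (glycolysis), 0.048 (antigen presentation) and 0.010 (MAP kinase). The mean of all probe sets gave -0.022 (SRC family), -0.063 (p53) and 0.014 (matrix). Array weights gave 0.19 (SRC family), -0.042 (p53) and 0.20 (matrix). Median centring gave -0.15 (glycolysis) and -0.018 (p53). Fry, which leaves the medians as reported, turned -0.066 (fatty acid oxidation), -0.045 (glycolysis), 0.35 (immune) and 0.089 (p53). The fits that left out 1 array or both named arrays ranged over -0.20 to 0.087 (fatty acid oxidation), -0.25 to -0.051 (glycolysis), 0.15 to 0.26 (SRC family), -0.14 to 0.19 (p53), 0.085 to 0.20 (matrix) and -0.45 to 0.089 (MAP kinase).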

Other observations

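Other gene families, chosen after their values were seen, held more members changed by at least 2-fold in the direction tested than chance would draw. Of 15 measured genes of the protocadherin beta cluster, cell adhesion genes that lie side by side, 12 were lower by at least 2-fold in 159/SUM159, where 2.14 would be drawn by chance (median -2.32, one-sided Fisher's exact test, adjusted p = 1.83e-07). Proteasome subunits had 25 of 34 genes lower by at least 2-fold (median -1.16, adjusted p = 1.59e-13), COMMD genes 8 of 10 (median -1.57, adjusted p = 3.46e-05), LSM genes 9 of 13 (median -1.76, adjusted p = 4.44e-05) and TIMM genes 9 of 16 (median -1.15, adjusted p = 0.000378). The MAGE, SSX and SPANX cancer-testis families had 9 of 21 lower (median -0.31, adjusted p = 0.0031), among them MAGEC2, SSX1 and SPANXB1. Near-identical copies in these families share probes. Higher by at least 2-fold were 4 of 7 IGFBP genes, IGFBP2, IGFBP4, IGFBP5 and IGFBP7 (adjusted p = 0.00112), and 10 of 43 collagen genes (median 0.17, adjusted p = 0.000686), while 6 collagen genes were lower. Of 425 zinc finger (ZNF) genes 41 were higher by at least 2-fold, where chance would draw 26.2 (median 0.19, adjusted p = 0.00626). Only 19 were lower, where chance would draw 60.5. Both the lower and the higher families were read on the arrays with the larger actin 3′ excess, 4.81 against 1.55. These families were picked for their changes, so the p-values overstate the evidence.

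The test of neighbouring genes and its RNA quality test were chosen after the result was seen, and the test of the other probe sets before. In windows of 50 neighbouring genes in GRCh38.p14 order, one run on chromosome 18, from USP14 to ROCK1, had a median difference of 1.10, against 0.55 for the next highest of 235 windows. In it 43 of 50 genes lay above 0, 35 were called higher and 3 lower (EPB41L3, LAMA1 and ROCK1). Among the higher were ANKRD12 at 3.76, RAB12 at 3.20, SPIRE1 at 2.87, YES1 at 2.46 and AFG3L2 at 1.91. Except for YES1 and AFG3L2, these genes were named after their values were seen. Chance order is argued against, since shuffled orders never reached this median (permutation p = 1e-04, the smallest that 10000 shuffles give). Shuffling does not allow for wider regional shifts, and every chromosome 19 window had a positive median (0.14 to 0.50). Those windows also read higher on 159/SUM159 replicates 2 and 3 than on replicate 1. The run read -0.25 on 159/SUM159 replicates 2 and 3 relative to replicate 1, at the 20th percentile of all windows, and its slope on actin excess was -0.32 (95% interval -1.07 to 0.44, needed 0.34), which does not settle whether RNA quality contributed. The 51 probe sets of these genes not used in the test had a median of 0.93, but they read the same transcripts and so do not separate copy number from another cause. Other windows were lower: 2 of them, RALGAPA1 to GMFB on chromosome 14 (-1.20, 35 lower and 6 higher) and ANTXR2 to PPP3CA-DT on chromosome 4 (-1.08, 28 lower and 7 higher), lay below every shuffled order (lowest -1.05). On 159/SUM159 replicates 2 and 3 relative to replicate 1 these 2 windows read -0.53 and -0.48, below the 2.5th percentile of all windows (-0.47). As an untested hypothesis, the 159/SUM159 cells may carry more copies of the chromosome 18 region than the A1/SUM159 cells. That would mean that the nuclear genomes of the groups differ beside their mitochondria, and no DNA measurement was analysed here.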
